A study of Mus musculus with 6 samples.

How the data were processed

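Total RNA of 6 mouse samples was labelled and hybridised to 1 Affymetrix array each, per the labels' protocols; biotin is named as the label for the wild-type samples only. The labels give 3 granulosa cell tumors of Smad1/5/8 mutant mice and 3 samples of wild-type granulosa cells of C57BL/6J;129S5/SvEvBrd females aged 21 days, collected 44 to 46 hours after PMSG injection and pooled from 2 to 3 females. The series' design text calls the tumors independent of each other; strain, age and sex of the tumor mice are not given in the sources used here, and the labels state that the tumors had no treatment. Per the labels' protocols, tumors were kept in an RNA storage solution overnight, frozen and extracted with an RNeasy kit, while wild-type RNA was extracted with RNeasy and treated with DNase on the column. The p-values below set group differences against the spread between these samples. Each wild-type sample is a pool, so the variation between single wild-type females was not measured.

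The deposited values are linear array intensities, 1 signal per probe set and array. Per the submitters' processing notes they come from MAS5 for the wild-type arrays and GCOS for the tumor arrays, with no version given. The deposited values had a trimmed mean of 500 on every array, with 2% of the values left out at each end, and medians between 100.6 and 127.8. Each array was scaled to that trimmed mean again, which moved almost nothing. Detection calls and scanner images were not used here. The probe-gene table was GEO's platform annotation. Of 45101 probe sets, 64 were control probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none; the 34945 named 18193 genes, and 34741 of them had an Entrez identifier found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. No genome was used, and no coordinates are printed. That table also gave the order of neighbouring genes.

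Values were tested as log2(signal + 32). A probe set passed the filter with a signal of at least 100 on at least 3 of the 6 arrays. Among a gene's passing probe sets with 1 symbol, the probe set with the highest mean signal stood for the gene, which left 11611 genes. The signal minimum of 100 lay close to the highest signal of the bacterial control probe sets whose transcripts had not been added in the hybridisation mix (101). Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) and called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Fold changes are on the log2(signal + 32) scale, which understates the change of dim genes. Where all 3 arrays of the dimmer group lay below 100, the fold is given as "at least", from the mean log2 signal of the brighter group against the dimmer group with each array set to 100. Where only some of these arrays lay below 100, the log2 fold change is given, and its size depends on the pseudocount. Values in the text are means ± SD of the signals over 3 arrays, and SE is limma's standard error of the log2 fold change. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

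Lists of genes were fixed before the data were examined: 31 lists with 712 entries, of which 644 were named on the array and 545 tested. They cover pathways of the mutated Smads, granulosa functions, tumor processes and markers of other cell types, and some genes stand on several lists. The 28 lists with at least 5 tested genes were tested with camera (limma, 2-sided, preset correlation 0.01) and adjusted by Benjamini-Hochberg over these lists. The list of Smad1, Smad5 and Smad9 was not tested as a list. Camera was repeated with a correlation estimated per list and on ranks, and fry was run as well. With the preset correlation, 15 lists were called; with the estimated correlation 0 were (3 at an unadjusted p under 0.05, lowest adjusted p 0.141), by ranks 14 and by fry 16. With the estimated correlation, the adjusted p also rose in the granulosa and Hedgehog lists, whose estimated correlations lay below 0.01. The adjusted p with an estimated correlation therefore does not measure the effect of correlated genes alone. The counts "adjusted over the list alone" use Benjamini-Hochberg within the list.

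Named genes followed a rule fixed before the data were examined. It takes Smad1, Smad5 and Smad9, and the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap and whose higher mean signal was at least 500, leaving out probe sets with several or no symbols. From each list it takes the 2 called members with the largest absolute change and the called member with the largest change in the other direction, or, with 0 called, the member with the smallest p. The rule gave 77 genes; 26 of them had over 1 passing probe set, and 1, Xaf1, had a passing probe set that went the other way. Genes named outside the rule are marked as chosen after their values were seen.

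The fit and the list tests were tested on simulated data for the 11611 genes, with variances drawn from the distribution that limma fitted to them. Of 100 genes changed by 1 on the log2 scale, 23 were called, and of 100 changed by 2, 86 were called, each in the right direction; 5 unchanged genes were called, 4.39% of the calls. No other genes were changed in that simulation, whereas 27.16% of the tested genes were called in the data. The Benjamini-Hochberg threshold depends on the share of changed genes, so these detection rates do not carry over to the data. A shifted list was called with the preset and the estimated correlation, and 0 of 25 unshifted lists were. The simulated genes were drawn independently of each other, whereas the estimated correlation was 0.694 in the mitosis list and 0.949 in the MHC class II list. The simulation therefore does not show how often lists of correlated genes are called falsely with the preset correlation.

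Alternatives fixed before the data were examined were no rescaling, quantile normalization, scaling to the same median, pseudocounts of 1 and 100, no filter, a filter at 200, the mean of a gene's probe sets, no probe sets marked as shared between transcripts (suffixes _x_at and _s_at), each probe set tested on its own, eBayes with a trend and robust variances, array weights, a test against a log2 change of 1 (treat), the replicate number as a block, and leaving out each sample in turn. Scaling to the 18 bacterial hybridisation controls was added after these controls were seen to differ between the groups. With 1 sample left out, the filter still asked for 3 arrays, so a gene bright in 1 group only could drop out or be represented by another of its probe sets. An alternative that kept the probe sets of all 6 arrays for the named genes was therefore added after the data were seen. Batch and group cannot be told apart here, since each group has its own protocol and software.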

Results

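Expression was measured on 6 oligonucleotide arrays of 45101 probe sets, each array carrying RNA of 1 mouse sample. 3 samples were granulosa cell tumors of mice mutant for Smad1, Smad5 and Smad8 (Smad9 in current nomenclature), the transcription factors through which bone morphogenetic protein (BMP) receptors signal. The other 3 were wild-type granulosa cells, the somatic cells that surround the oocyte in a follicle. These cells were isolated from 21-day-old females primed for 44 to 46 hours with pregnant mare serum gonadotropin (PMSG), a hormone preparation with follicle-stimulating activity, and each sample pooled 2 to 3 females. Every array had a trimmed mean signal of 500 in the deposited values, and between 22565 and 25021 probe sets reached a signal of 100 on an array. Pearson correlations across the 11611 tested genes were 0.964 to 0.979 between wild-type samples, 0.938 to 0.951 between tumors and 0.841 to 0.867 across the groups. Genes are not independent replicates, so these correlations carry no test. The number of arrays, 3 per group, limits the precision of every value.

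The comparison asked which genes differ between tumors of the mutant mice and wild-type granulosa cells. Tumors had lower signals of the activin subunit genes Inhba and Inhbb, of the BMP-responsive gene Id3, and of 13 of 23 genes induced by PMSG, 14 of 20 cholesterol synthesis and uptake genes and 22 of 31 mitosis genes. They had higher signals of the Hedgehog effector gene Gli1, of 19 of 21 macrophage, 15 of 15 smooth muscle, 18 of 25 fibroblast and 12 of 22 endothelial markers, and of 10 of 25 TGF-beta target genes. Of 28 gene lists, 15 shifted with camera's preset correlation and 0 with a correlation estimated from the data (3 at an unadjusted p under 0.05). Inhba fell by 5.42 on the log2 scale (limma SE 0.48, n = 3 per group), from a mean signal of 26368 ± 5592 (SD) to 687 ± 499. Gli1 rose at least 6.24-fold, and C1qc, a complement gene of macrophages, rose by 3.50 (SE 0.55). Of the 11611 genes tested, 1686 were higher and 1468 lower in tumors at a Benjamini-Hochberg adjusted p under 0.05 in limma, and 968 and 613 of these changed at least 2-fold on the log2(signal + 32) scale. The 3 tumor values lay all above or all below the 3 wild-type values in 5373 genes, 46.3% of those tested, where chance gives 10%.

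The groups differed in more than genotype. Tumor tissue was set against isolated cells, wild-type mice alone were primed, the protocols name a storage solution for the tumor tissue alone, and the groups' signals came from different software, so these differences and the genotype cannot be told apart. The log2 ratio of the 3' to the 5' control probe sets of Actb, a sign of RNA quality, was 0.447 ± 0.193 (SD, n = 3) in wild-type samples and 0.808 ± 0.209 in tumors, while that of Gapdh was -0.391 ± 0.0653 and -0.365 ± 0.113. Without 1 sample at a time, the counts ranged from 886 (without wild-type replicate 1) to 1507 higher genes and from 596 (again without wild-type replicate 1) to 1421 lower genes. The higher count also moved by over 1.5 times without wild-type replicate 3 (1113) or tumor replicate 2 (1049), and the lower count without wild-type replicates 2 (901) and 3 (820). Scaled to the bacterial hybridisation controls, an alternative chosen after seeing the data, the split was 377 higher and 7801 lower.

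Smad1, Smad5 and Smad9 were measured by 7 probe sets. Smad1 and Smad5 signals were higher in the arrays labelled tumor: 5 of their 6 probe sets had all 3 tumors above all 3 wild-type samples. The brightest Smad1 probe set read 829.6, 855.6 and 925.7 in the wild-type samples and 2076, 2861 and 2354 in the tumors, a log2 fold change of 1.44 (SE 0.16, limma adjusted p = 0.00169). The brightest Smad5 probe set read 1246, 1078 and 1273 against 2435, 2815 and 3108, a log2 fold change of 1.19 (SE 0.16, limma adjusted p = 0.00276). The other Smad1 probe sets had log2 fold changes of 1.11 and 1.04, and those of Smad5 0.45 and 0.41, which did not pass when each probe set was tested. The Smad5 probe set at 0.41 is among the 5 without overlap, though its lowest tumor signal was 293.6 and its highest wild-type signal 292.6. The Smad9 probe set stayed below 100 on every array, with means of 52.0 ± 41.3 and 37.5 ± 30.0 (SD, n = 3). How the genes were mutated and where these probe sets lie relative to the mutated parts is not given in the sources used here, and a probe set outside a mutated part does not check the labels. Scaled to the hybridisation controls, neither call held (log2 fold change 0.41 for Smad1 and 0.16 for Smad5), with the median of all genes at -1 under that scaling.

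**Figure D1:**
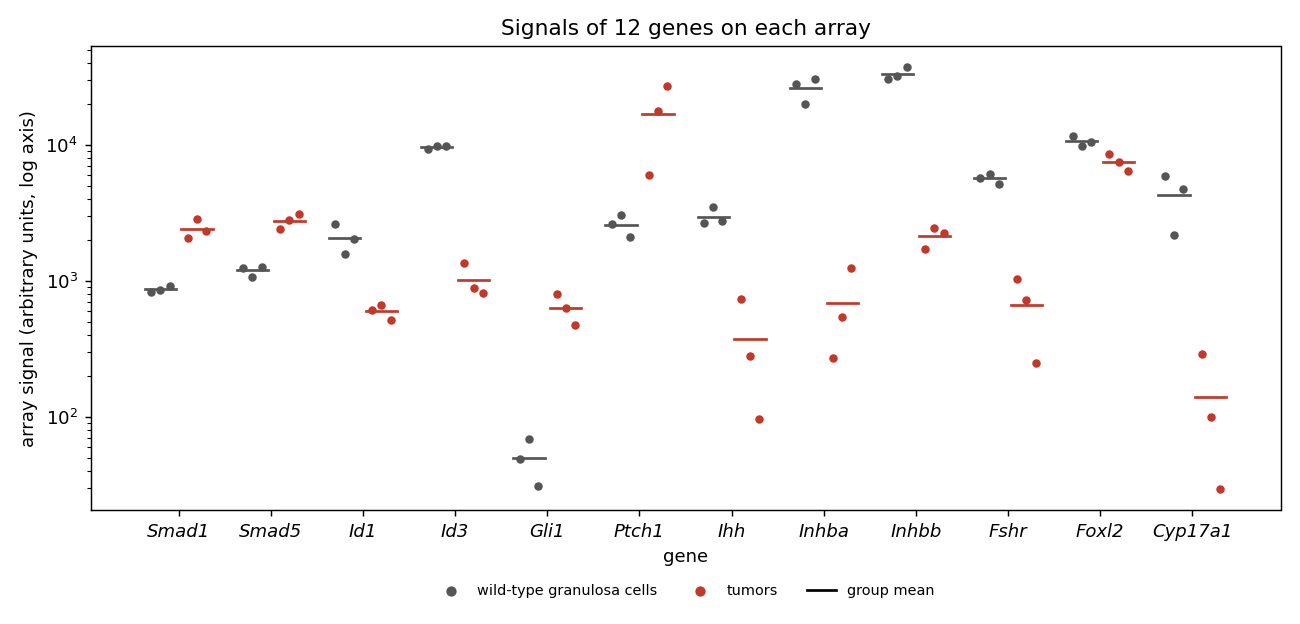
Array signals (arbitrary units, log axis) of 12 genes in 3 wild-type granulosa cell samples (grey) and 3 tumors (red). Each point is 1 array and each line a group mean. For 11 of the genes the groups differ at a limma adjusted p under 0.05, with no overlap between the groups; Foxl2, at means of 10676 and 7546, did not pass.

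Among the 22 tested genes of BMP signalling, 7 rose, 6 fell and 9 did not pass, and the list as a whole did not shift (camera adjusted p = 0.755; adjusted p = 0.865 with an estimated correlation). Adjusted over the list alone, 8 were higher and 7 lower. Id3, an inhibitor of DNA binding induced by BMP-activated Smads in many cells, fell from 9714 ± 321 to 1018 ± 288 (SD, n = 3), a log2 fold change of -3.25 (SE 0.21, limma adjusted p = 0.000254). Its relative Id1, chosen after its values were seen, fell from 2085 ± 537 to 599 ± 71.9, a log2 fold change of -1.72 (SE 0.21). The Id genes did not all fall, by values also chosen after they were seen. Id4 was higher in tumors, at means of 59.5 and 241 (limma adjusted p = 0.0242), and Id2 did not pass (log2 fold change 0.18, limma adjusted p = 0.583). The secreted BMP antagonist gene Grem1, also on the list of PMSG-induced genes, fell by 4.54 on the log2 scale (SE 0.34, limma adjusted p = 0.000454). Bmper, which encodes a BMP-binding protein, rose from 652 ± 133 to 3958 ± 165 (log2 fold change 2.56, SE 0.18).

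Of 23 ligand, receptor and Smad genes of the activin, inhibin and TGF-beta branches, 6 rose, 5 fell and 12 did not pass, with no shift of the list (camera adjusted p = 0.803; adjusted p = 0.896 with an estimated correlation). Adjusted over the list alone, 7 were higher and 5 lower. Inhbb, the gene of the other activin subunit, fell from 33400 ± 3681 to 2139 ± 380 (SD, n = 3), a log2 fold change of -3.95 (SE 0.18, limma adjusted p = 0.000162). Fstl1, a follistatin-like gene, rose by 2.00 on the log2 scale (SE 0.22). The TGF-beta target genes shifted higher as a list: 10 of 25 rose, 2 fell and 13 did not pass, and 12 and 3 passed adjusted over the list alone. Its camera adjusted p was 0.000447, against an adjusted p = 0.32 with an estimated correlation. Postn, a matrix gene also on the fibroblast list, rose by 3.57 (SE 0.43) and Tgfbi by 3.25 (SE 0.28), while Thbs1 fell by 1.38 (SE 0.34, limma adjusted p = 0.0241). The Thbs1 call was lost without any of 5 of the 6 samples, tumor replicate 3 being the exception, with adjusted p up to 0.0755 over the 6 fits.

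Hedgehog pathway genes changed in both directions. Of 14 tested, 7 rose, 3 fell and 4 did not pass, over all genes and adjusted over the list alone, and the list's camera adjusted p of 0.0531 missed the threshold (adjusted p = 0.32 with an estimated correlation). It passed under 9 of 21 alternatives, with adjusted p from 0.00238 to 0.105; among these were the fits without wild-type replicate 1 (0.0236) and without wild-type replicate 3 (0.0293). Gli1, a transcription factor gene induced by Hedgehog signalling, was below 100 on all 3 wild-type arrays and rose to 638 ± 162 (SD, n = 3), at least 6.24-fold (limma adjusted p = 0.000582). Gli2 and the receptor gene Ptch1, both chosen after their values were seen, rose by 3.00 (SE 0.32) and 2.47 (SE 0.51). Gli1 and Ptch1 also stand on the theca and interstitial list and are among the genes of that list that rose. The ligand gene Ihh, which granulosa cells express, fell from 2973 ± 477 to 373 ± 334, a log2 fold change of -3.24 (SE 0.58, limma adjusted p = 0.0082). Wnt target genes shifted higher, with 8 of 15 up, 1 down and 6 that did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.00393; adjusted p = 0.32 with an estimated correlation). Rspo1, which encodes a secreted enhancer of Wnt signalling, rose by 2.49 (SE 0.52), and Sfrp4, a secreted Wnt-binding protein gene, fell by 2.22 (SE 0.64, limma adjusted p = 0.0403). Sfrp4 lost its call without any wild-type sample or tumor replicate 2, with adjusted p up to 0.115 over the 6 fits. With its probe set kept, Rspo1 lost its call without wild-type replicate 1 (limma adjusted p = 0.0507).

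Genes of granulosa cell identity fell more often than they rose: 7 of 22 were lower, 3 higher and 12 did not pass, and 9 and 5 passed adjusted over the list alone. The camera adjusted p was 0.0398 (adjusted p = 0.32 with an estimated correlation). It rose to 0.0623 without wild-type replicate 2, to 0.0701 without tumor replicate 2, to 0.0637 by ranks and to 0.0506 with the filter at 200. Over 21 alternatives, fry among them, the list's adjusted p ranged from 0.00302, given by fry, to 0.0701. Slc18a2, a monoamine transporter gene, rose from 3647 ± 1235 to 31992 ± 4326 (SD, n = 3), a log2 fold change of 3.17 (SE 0.27, limma adjusted p = 0.000629). Among genes chosen after their values were seen, Fshr, the receptor gene for follicle-stimulating hormone, fell by 3.23 (SE 0.45, limma adjusted p = 0.0036), and Foxl2, a transcription factor gene of granulosa cells, had a log2 fold change of -0.51 (SE 0.16, limma adjusted p = 0.0583). Foxl2 passed without tumor replicate 1 (adjusted p = 0.049).

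Genes that PMSG or follicle-stimulating hormone induces in preovulatory follicles were lower in tumors, 13 of 23, and the other 10 did not pass; 14 were lower adjusted over the list alone. The camera adjusted p was 2.51e-06 (adjusted p = 0.141 with an estimated correlation). Comp, a matrix gene, fell from 10825 ± 2149 to 81.1 ± 60.2 (SD, n = 3; limma adjusted p = 0.000242). With tumor signals around 100 the size of the Comp change depends on the pseudocount: the log2 fold change was -6.73 with 32, -7.41 with 1 and -5.95 with 100. Inhba stands on this list, on the granulosa list and on the activin list. Only the wild-type mice were primed. Of 10 tested genes induced by luteinizing hormone, 2 rose, 2 fell and 6 did not pass, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.755; adjusted p = 0.865 with an estimated correlation). The median log2 fold change of that list was -0.04, its mean 0.07 and its camera direction downward. Rgcc rose by 1.77 (SE 0.38), Adamts1, a protease gene of the ovulating follicle, fell by 1.76 (SE 0.18), and Pgr, the progesterone receptor gene, rose by 1.93 (SE 0.49, limma adjusted p = 0.0273). The Pgr call was lost without any wild-type sample or tumor replicate 3, with adjusted p up to 0.0831 over the 6 fits.

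Steroidogenic genes fell as a list, with 9 of 16 lower, 2 higher and 5 that did not pass (camera adjusted p = 0.0134; adjusted p = 0.43 with an estimated correlation); adjusted over the list alone, 9 were lower and 3 higher. Of the 16, 4 also stand on the PMSG list (Cyp11a1, Fdx1, Star and Hsd17b1), and the wild-type mice alone were primed. Cyp11a1, the enzyme that cleaves the cholesterol side chain, fell from 12991 ± 2719 to 909 ± 1103 (SD, n = 3), a log2 fold change of -4.45 (SE 0.74, limma adjusted p = 0.00638). Cyp17a1, an enzyme of androgen synthesis in theca cells, fell by 4.85 (SE 0.62). Hsd11b1, which reactivates glucocorticoids, rose at least 4.42-fold (limma adjusted p = 0.00885). Of 20 cholesterol synthesis and uptake genes, 14 fell, 0 rose and 6 did not pass, and 15 were lower adjusted over the list alone (camera adjusted p = 2.08e-07; adjusted p = 0.337 with an estimated correlation). Fdps, a prenyl diphosphate synthase gene, fell from 9282 ± 2089 to 2289 ± 597 (SD, n = 3; log2 fold change -2.01, SE 0.25), and Tm7sf2, a sterol reductase gene, fell by 1.95 (SE 0.34).

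Mitosis genes were lower in tumors: 22 of 31 fell, 0 rose and 9 did not pass, and 24 were lower adjusted over the list alone (camera adjusted p = 2.05e-09; adjusted p = 0.43 with an estimated correlation). The list's median log2 fold change was -0.87. Bub1, a spindle checkpoint kinase gene, fell from 2848 ± 81.2 to 886 ± 227 (SD, n = 3), a log2 fold change of -1.68 (SE 0.21, limma adjusted p = 0.00224). Mad2l1, of the same checkpoint, fell by 1.61 (SE 0.29). Of 31 DNA replication genes, 7 fell, 0 rose and 24 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.000698; adjusted p = 0.573 with an estimated correlation). Fry, which asks whether the genes move on balance 1 way, gave an adjusted p = 0.143 for that list, the highest of a range from 1.63e-05 over 21 alternatives. Gins1 fell by 1.19 (SE 0.30, limma adjusted p = 0.0254) and Ccne2 by 0.87 (SE 0.18, limma adjusted p = 0.0132). Both calls were lost without wild-type replicate 1 (adjusted p = 0.0815 and 0.0588, the highest of the 6 fits without 1 sample), and that of Gins1 also without either of the other wild-type samples or tumor replicate 2. The log2 3' to 5' ratio of Actb was higher in the tumors, as given above, while that of Gapdh was similar (-0.391 in wild-type samples and -0.365 in tumors). A link between these ratios and the genes of these lists was not tested.

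**Figure D2:**
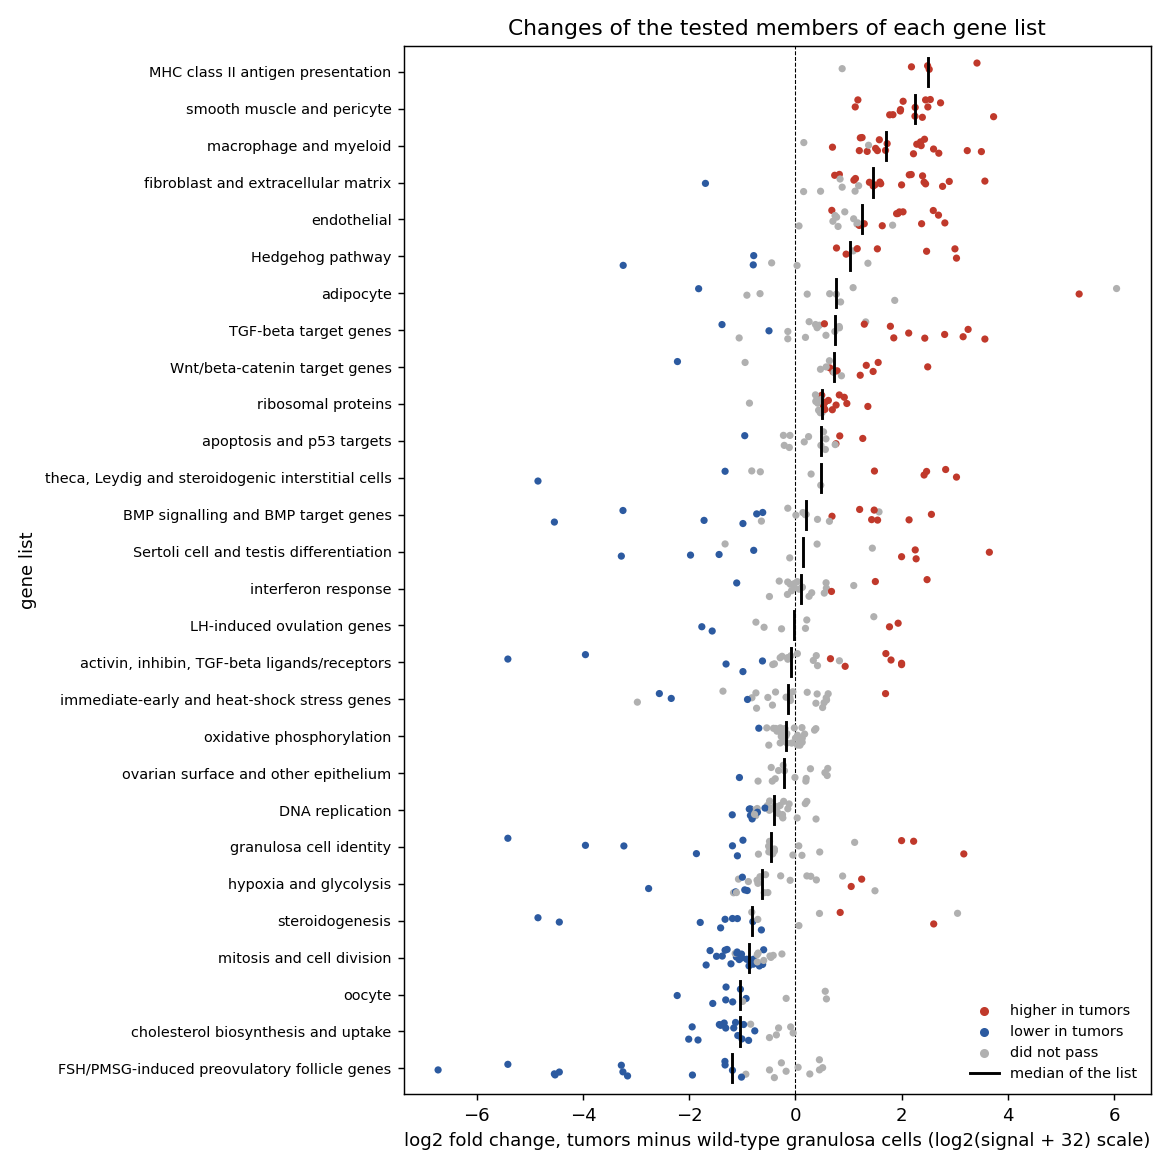
Log2 fold change (tumors minus wild-type granulosa cells, log2(signal + 32) scale) of every tested member of the 28 gene lists with at least 5 tested genes, ordered by list median. Points are genes, coloured by whether they were higher (red), lower (blue) or did not pass (grey) at a limma adjusted p under 0.05, and black bars are list medians, which run from -1.19 for the PMSG-induced genes to 2.49 for the MHC class II genes.

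Markers of other cell types differed between the groups. Macrophage and myeloid genes were higher in tumors, 19 of 21 with 0 lower and 2 that did not pass, the same counts adjusted over the list alone (camera adjusted p = 6.61e-12; adjusted p = 0.141 with an estimated correlation). C1qa rose from 176 ± 82.5 to 1860 ± 547 (SD, n = 3), a log2 fold change of 3.24 (SE 0.34, limma adjusted p = 0.00137). All 15 smooth muscle and pericyte genes rose (camera adjusted p = 7.03e-09; adjusted p = 0.32 with an estimated correlation), and all 15 passed adjusted over the list alone. Rgs5, a pericyte gene, rose from 195 ± 84.2 to 3396 ± 2007, a log2 fold change of 3.73 (SE 0.55), and Cnn1, a smooth muscle gene, by 2.73 (SE 0.53). Of 25 fibroblast and extracellular matrix genes, 18 rose, 1 fell and 6 did not pass, with 21 and 1 adjusted over the list alone (camera adjusted p = 7.03e-09; adjusted p = 0.164 with an estimated correlation). Lum, a matrix proteoglycan gene, rose by 2.90 (SE 0.41), and Fbln1, a fibulin gene, fell by 1.69 (SE 0.18). Endothelial genes rose in 12 of 22 cases, with 0 lower and 10 that did not pass, and 17 were higher adjusted over the list alone (camera adjusted p = 1.12e-07; adjusted p = 0.337 with an estimated correlation). Sox18, an endothelial transcription factor gene, rose by 2.81 (SE 0.32). Vwf rose at least 4.72-fold (limma adjusted p = 0.0136), with unequal tumor signals of 266.7, 1116 and 354.2.

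MHC class II genes rose in 4 of 5 cases and 1 did not pass, and all 5 passed adjusted over the list alone (camera adjusted p = 0.00566; adjusted p = 0.43 with an estimated correlation). H2-Aa rose by 3.42 (SE 0.53), and Cd74, at 7654, 1447 and 1077 in the tumors against a wild-type mean of 377 ± 59.0 (SD, n = 3), by 2.52 (SE 0.67, limma adjusted p = 0.0308). The Cd74 call was lost without any wild-type sample, with adjusted p up to 0.0908 over the 6 fits. Of 4 tested lymphocyte genes, too few for a list test, Ighm and Jchain rose and 2 did not pass, and 3 were higher adjusted over the list alone. With no filter on low signals the lymphocyte list could be tested and did not shift (median log2 fold change 0.23, camera adjusted p = 0.123, the 1 alternative with a value). Ighm read 8275, 133.8 and 1209 in the tumors and stayed below 100 in the wild-type samples, at least 11.0-fold above these (limma adjusted p = 0.0434). With this probe set kept in each fit, an alternative chosen after seeing the data, the Ighm call was lost without tumor replicate 1 or 3 or any wild-type sample, with log2 fold changes from 2.81 to 5.63 and adjusted p up to 0.112 over the 6 fits. With the filter applied anew without tumor replicate 1, that probe set failed and another one stood for Ighm, with a log2 fold change of 0.09 (adjusted p = 0.789). With all samples, the other Ighm probe sets past the filter had log2 fold changes of 1.12, 2.93 and 1.02. None of them was called when each probe set was tested (limma adjusted p = 0.429, 0.0555 and 0.334). The Ighm bound was 4.02-fold without tumor replicate 1 and 31.6-fold without tumor replicate 2. Jchain, at least 8.01-fold higher (limma adjusted p = 0.046; 3.51-fold without tumor replicate 1 and 16.8-fold without tumor replicate 2), lost its call without any wild-type sample and, with its probe set kept, without tumor replicate 3, with adjusted p up to 0.122.

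Oocyte genes fell, 7 of 11 with 4 that did not pass, and 8 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00609; adjusted p = 0.32 with an estimated correlation). That shift was lost without wild-type replicate 1 (adjusted p = 0.345), 2 (0.456) or 3 (0.219), within a range of 0.00427 to 0.456 over 20 alternatives. The filter still asked for 3 arrays there, so oocyte genes below 100 in the tumors dropped out of these fits. The list was not tested with its probe sets kept, so how much of the loss comes from the filter is not known. Zp3, a gene of the egg coat, was at least 2.67-fold higher in wild-type samples than in tumors (limma adjusted p = 0.00698). With its probe set kept, Zp3 was called in every fit without 1 sample (limma adjusted p up to 0.0322). Ooep, another oocyte gene, fell by 1.56 (SE 0.39, limma adjusted p = 0.0254) and lost its call without any wild-type sample, with adjusted p up to 0.0799. Epithelial genes gave 1 fall among 15 and 14 that did not pass, and 0 adjusted over the list alone (camera adjusted p = 0.563; adjusted p = 0.881 with an estimated correlation); the 1 was Upk3b, at -1.05 (SE 0.29, limma adjusted p = 0.0365), which lost its call without any of 4 of the samples (adjusted p up to 0.107). Of 11 theca and interstitial genes, 5 rose, 2 fell and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.22; adjusted p = 0.573 with an estimated correlation). Sertoli cell genes, 12 tested, split 4 to 4, and 5 to 5 adjusted over the list alone (camera adjusted p = 0.907; adjusted p = 0.908 with an estimated correlation). Ptgds, a prostaglandin synthase gene, rose by 3.65 (SE 0.25) and Mro, also on the PMSG list, fell by 3.28 (SE 0.36). Of 11 adipocyte genes, Fabp4 rose, Pparg fell by 1.82 (SE 0.36) and 9 did not pass, over all genes and adjusted over the list alone. The adipocyte list's camera adjusted p of 0.357 (adjusted p = 0.822 with an estimated correlation) dropped to 0.00287 without tumor replicate 2, in a range of 0.00285 to 0.986 over 21 alternatives. Of 2 tested erythroid genes, neither passed, and with no filter the list did not shift (camera adjusted p = 0.551, the 1 alternative with a value). Alas2 had a log2 fold change of -0.84 (SE 0.94), which ran from -1.625 to 0.3394 over the fits without 1 sample and so changed sign.

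Ribosomal protein genes were higher in tumors in 12 of 22 cases, 10 did not pass, and 19 were higher and 1 lower adjusted over the list alone (camera adjusted p = 6.11e-06; adjusted p = 0.43 with an estimated correlation). Under quantile normalization the list's median log2 fold change dropped from 0.50 to 0.08 and its adjusted p rose to 0.155, the highest of a range from 2.36e-07 over 21 alternatives. Rps6 rose by 1.36 (SE 0.22, limma adjusted p = 0.00625) and Rpl14 by 0.97 (SE 0.18). Hypoxia and glycolysis genes gave 2 higher, 5 lower and 17 that did not pass (camera adjusted p = 0.0941; adjusted p = 0.738 with an estimated correlation). That list passed without wild-type replicate 2 (adjusted p = 0.0444) and without tumor replicate 2 (0.00119), in a range of 0.00119 to 0.345, the latter by fry, over 21 alternatives. Slc16a3, a lactate transporter gene, fell by 2.76 (SE 0.66, limma adjusted p = 0.022) and lost its call without any 1 of 4 samples, with log2 fold changes from -3.61 to -2.32 and adjusted p up to 0.0706 over the 6 fits. Ndrg1 rose by 1.25 (SE 0.26), a call lost without wild-type replicate 1 (adjusted p = 0.0583).

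Of 24 immediate-early and stress genes, 1 rose, 3 fell and 20 did not pass (camera adjusted p = 0.342; adjusted p = 0.865 with an estimated correlation); Fos fell by 2.56 (SE 0.54), Ier2 fell by 2.34 (SE 0.43) and Klf2 rose by 1.70 (SE 0.36), a call lost without wild-type replicate 1 (adjusted p = 0.056). Of 15 p53 targets, 3 rose, 1 fell and 11 did not pass (camera adjusted p = 0.0941; adjusted p = 0.573 with an estimated correlation), and the list passed without tumor replicate 3 (adjusted p = 0.016, the lowest of 21 alternatives that reached 0.217). Phlda3 rose by 1.27 (SE 0.25) and Perp fell by 0.95 (SE 0.22); both calls were lost without wild-type replicate 1, and that of Perp without tumor replicate 2, with adjusted p up to 0.0506 and 0.0566. Interferon response genes gave 3 higher, 1 lower and 18 that did not pass (camera adjusted p = 0.348; adjusted p = 0.516 with an estimated correlation). Xaf1 rose by 2.48 (SE 0.31), although another of its probe sets went the opposite way without passing, Ifit2 rose by 1.51 (SE 0.17) and Stat2 fell by 1.11 (SE 0.16). Of 30 oxidative phosphorylation genes, 29 did not pass and Ndufa4 fell by 0.69 (SE 0.14), a call lost without wild-type replicate 1 (adjusted p = 0.0599, the highest of the 6 fits) and, with the probe sets kept, without wild-type replicate 3; the list's camera adjusted p was 0.125 (adjusted p = 0.738 with an estimated correlation), and 0.0366 without wild-type replicate 2, in a range of 0.0199 to 0.375 over 21 alternatives. Adjusted over the list alone, the counts of the hypoxia, immediate-early, p53 and interferon lists were the same, and that of the oxidative phosphorylation list was 0.

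The 10 highest and the 10 lowest log2 fold changes were taken among genes past the threshold with no overlap between the groups and a mean signal of at least 500 in the higher group. Klhl40, best known from skeletal muscle, was below 100 in all wild-type samples and reached 3620.2 ± 1562 (SD, n = 3) in tumors, at least 33.8-fold (limma adjusted p = 0.000316). Fabp4, a fatty acid binding protein gene of adipocytes, rose by 5.34 (SE 1.09, limma adjusted p = 0.0129), with tumor signals of 12180, 745.7 and 18320. Rises of over 4 on the log2 scale were also found for the kinase gene Mapk10 (4.50, SE 0.28), Tmem184a (4.17, SE 0.26) and Eya4, a transcriptional cofactor gene (4.04, SE 0.34). The immunoglobulin genes Igkv8-30, at least 26.7-fold, and Igha (log2 fold change 4.18, SE 0.79) belong to families with near-identical copies, which a probe set may not separate. Igkv8-30 read 13340, 348 and 4108 in the tumors, and its bound was 12-fold without tumor replicate 1 and 74.0-fold without tumor replicate 2. With its probe set kept in each fit, it lost its call without any wild-type sample or tumor replicate 3 (adjusted p up to 0.065). Thrsp, at least 12.8-fold, and Srpx2, at least 12.3-fold, complete the 10 highest together with Ighm. Among the 10 lowest, Meg3, an imprinted long noncoding RNA, fell from 8693 ± 2555 to 160.2 ± 43.1 (SD, n = 3), a log2 fold change of -5.48 (SE 0.27, limma adjusted p = 0.000174). Masp1, a lectin pathway protease gene, fell by 4.86 (SE 0.15) and Crabp2, a retinoic acid binding protein gene, by 4.67 (SE 0.37). Jakmip3, Gabrb2, Tnfsf11 and Kcne2, each below 100 in all tumors, were higher in wild-type samples by at least 29.0-fold, 23.6-fold, 9.75-fold and 9.56-fold. The others, Comp, Inhba and Cyp17a1, are given above.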

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

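Of the tests below, those on the 3 patterns were chosen after the pattern was seen, as was the scaling to the hybridisation controls; the count of other splits was planned. Probe sets outside the comparisons carried signal that differed between the groups. The 18 bacterial hybridisation controls, transcripts added to each hybridisation mix, averaged 11.3 ± 0.167 (SD, n = 3) on the log2 scale on the wild-type arrays and 12.4 ± 0.439 on the tumor arrays, a difference of 1.05. Of 3167 tested probe sets with several or no gene symbols, 278 were higher and 380 lower in tumors. The samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05; only the real split, 1 of 10, gave as many called genes, 3154, and the highest of the others gave 0 (663 genes at an unadjusted p under 0.05 in limma, against 4668 for the real split).

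Smad1 and Smad5 signals were higher in the arrays labelled tumor, although the mice are labelled mutant for these genes. A swap of the labels of both groups would put the response to priming in the arrays labelled tumor, and 0% of the 13 called PMSG-induced genes were higher there, so the tables argue against it. All 3 tumors lay above all 3 wild-type samples in 5 of 6 Smad1 and Smad5 probe sets, as they did in 23.7% of all tested genes. In 1 of the 5, a Smad5 probe set, the lowest tumor read 293.6 and the highest wild-type sample 292.6. If the genes were deleted, probe sets outside the deleted part, or cells that kept the genes, could give such signals. Neither the kind of mutation nor the probe positions are known here, so these explanations, and a rise of mutated transcripts, stay open.

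Mitosis genes were lower in tumors than in wild-type cells. Scaling of the arrays as the cause is argued against by quantile normalization, under which the list's median log2 change was -0.905 and its camera adjusted p 1.99e-09 (adjusted p from 9.96e-12 to 0.023, the latter by fry, over 21 alternatives, and 0.43 with camera's estimated correlation). A lower share of granulosa cells in the tumors could be the whole cause only if granulosa genes fell as far: the mitosis median lay -0.624 ± 0.401 (SD over 3 tumors) from that of 18 granulosa identity genes outside the PMSG list, past the bound set for the test, but 3 of these rose and 5 fell with an SD of 1.76 over members, so the test stays undecided. Priming of the wild-type mice stays open as well, since 0 wild-type samples came from unprimed mice, and the tumor genotype, the age of the mice and the cell type are not separated from it.

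Stromal, vessel and macrophage markers were higher in tumors. Of the 83 tested members of the fibroblast, smooth muscle, endothelial and macrophage lists, 86.7% had all 3 tumors above all 3 wild-type samples, where chance gives 5% and all tested genes gave 23.7%; this share restates the rise and does not separate cells of these types in the tumor samples from a change of the tumor cells, so both stay open. Of these 83, 64 also averaged at least 100 in the wild-type samples and 2 stand on another list; the abundant Col3a1 and Acta2, chosen after their values were seen, averaged 16740 and 13520 in tumors against 6393 and 3599. Had a lower share of granulosa cells alone raised every other type alike, the smooth muscle and epithelial medians would have moved together. The smooth muscle median exceeded the epithelial one by 2.21 ± 0.24 (SD over 3 tumors), which argues only against an equal rise of all types. Types may rise unequally, and the epithelial gene Upk3b averaged 2027 in the wild-type samples, so a changed cell mixture stays open. The isolation of the wild-type cells, which would remove stromal, vessel and macrophage cells from that group only, was not tested.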

How the results depend on the processing

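Scaling to the hybridisation controls and keeping the probe sets without 1 sample were chosen after seeing the data; the other alternatives were planned. That scaling moved the median of all genes by -1 on the log2 scale and gave 377 higher and 7801 lower genes (283 and 5892 at least 2-fold); 4.61% of the calls were then higher, against 53.5%. Relative to that shift, 1 of 28 list medians changed sign (LH-induced genes) and 0 of 77 named genes did. Testing each probe set gave 2676 higher and 2884 lower (1650 and 1405 at least 2-fold), by construction from more tests, and treat against a log2 change of 1 gave 150 and 99, by construction a stricter test. Without 1 sample, with fewer samples by construction, higher genes ranged from 886 to 1507, lower genes from 596 to 1421, and genes at least 2-fold lower from 394 (without wild-type replicate 1) to 663. Shifted lists numbered 13 to 19 in the alternatives other than the estimated correlation. With an estimated correlation 0 were called, 0 higher and 0 lower (3 at an unadjusted p under 0.05 in camera). The estimated correlation was below the preset 0.01 in the granulosa (-0.0224) and Hedgehog (0.00432) lists. Their camera adjusted p still rose, from 0.0398 and 0.0531 to 0.32 each, which argues against correlated genes as the cause in these lists. That of the PMSG list, with a correlation of 0.0158, rose from 2.51e-06 to 0.141. Other lists had correlations up to 0.949. Since the adjusted p rose in lists with a lower correlation too, the settings differ in more than the correlation. The rise in the other lists can therefore not be read as an effect of correlated genes alone, and its cause was not tested. Besides the estimated correlation, 11 of 15 called lists kept their call in every alternative that tested them, and the granulosa, oocyte, ribosomal and DNA replication lists did not. The MHC class II list without shared probe sets, and both this list and the oocyte list with the filter at 200, had under 5 genes and no value. Of 13 lists not called, 6 were called in at least 1 alternative. The replicate block gave 1464 higher and 1138 lower genes and 16 lists; the numbers do not pair the samples (r of same-numbered deviations -0.0449, 0.0276 and 0.09). Leaving out the rescaling changed neither count of called genes. Of 1420 values of the 77 named genes, 1345 kept their call or their lack of a call, 74 lost the call, 1 gained it and 0 reversed with a call. A change of sign with no call in either fit, as for Alas2, is counted as kept. Without 1 sample, 59 of 76 called genes kept their call in each fit that tested them. Of these, 48 kept it in 6 fits and 11 in fewer, since the filter dropped them. With the probe sets kept, 58 kept it in 6 fits, and Rspo1 lost it without wild-type replicate 1 (adjusted p = 0.0507). Signals below about 100 lie among the controls that were not added, which limits dim genes.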

Other observations

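Of the test and genes below, Rian, Mirg and Car3 and the fits that kept their probe sets were chosen after the values were seen, while the bounds of the test on neighbouring genes were set before its result was known. Meg3 had 2 neighbours that moved with it. Rian, a noncoding RNA of the same imprinted region, fell from 1022 ± 163 to 40.6 ± 21.1 (SD, n = 3), at least 10.1-fold (limma adjusted p = 0.000232), and Mirg, a microRNA host transcript next to it, fell from 578 ± 120 to 46.1 ± 30.3, at least 5.69-fold (limma adjusted p = 0.00153). With these probe sets kept, both were called in each of the 6 fits without 1 sample (adjusted p up to 0.00245 for Rian and 0.00914 for Mirg). With the filter applied anew without wild-type replicate 2, the probe set failed and another one stood for Rian, with a log2 fold change of -1.86 (adjusted p = 0.0686). A loss of the whole chromosome region could lower all 3, and was tested on the 20 annotated protein-coding genes on each side. Of these, 25 were tested, 3 rose, 1 fell, and their median log2 fold change was 0.048 (SD 0.743), which argues against a loss that reaches these genes. Begain, Dlk1 and Dio3, the flanking genes nearest to the noncoding transcripts, and Rtl1, which lies among them, had no value. A loss that ends before the tested genes was therefore not examined. A change confined to the imprinted transcripts stays open as a hypothesis, with no test here of methylation or copy number.

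Tumors differed from each other in a few abundant transcripts. Car3, a carbonic anhydrase gene of adipocytes and muscle, read 22640, 119.6 and 29990 in the tumors and at most 66 in wild-type samples; it did not pass in limma (adjusted p = 0.0521). With its probe set kept, Car3 passed without tumor replicate 2 (adjusted p = 0.000621) and in no other fit without 1 sample (adjusted p up to 0.146). Fabp4 had the same order of tumors, at 12180, 745.7 and 18320. The immunoglobulin genes followed another order: Ighm read 8275, 133.8 and 1209, Igha 4898, 575.9 and 803.4, and Jchain 4170, 181.4 and 679.4.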
